A study of Mus musculus with 6 samples.

How the data were processed

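Total RNA from mouse pancreatic samples of 3 genotypes was sequenced, per the labels' protocols, after Trizol extraction and library preparation with a NEBNext Ultra RNA kit. The samples were WT 1 and WT 2, labelled as a control without KRAS and P53 mutations, KC 1 and KC 2 with a KRAS mutation, and KPC 1 and KPC 2 with KRAS and P53 mutations. The deposited values are raw read counts per gene, made by the authors by aligning reads to mm10 with STAR and counting with featureCounts of Subread, per the submitters' processing notes, which also name DESeq2. Those notes give no version of any tool, and the labels do not state a strand setting, so counts of genes that overlap on opposite strands may include reads of both. All counts were whole numbers, and every column was mapped to a sample by its name.

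The table held 38087 genes, 1481 of them with no count in any library. Gene symbols were matched by name to the GENCODE M21 annotation, which held 36756 of them and supplied coordinates and gene types. Groups, comparisons, the 28 gene lists, the rule for named genes and all alternatives but those named at the end were fixed before the data were examined. The comparisons were KC against WT, KPC against WT and KPC against KC, and the genes shared by the comparisons against WT. Replicate numbers are shared between groups, and no label says that a number marks an animal, litter or day, so no block was used.

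Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group (23906 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 6 samples, so that the 3 groups shared the estimate of spread. The common biological coefficient of variation was 0.602, with 3 residual and 3.55 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. CPM values are TMM-normalised, and log2 CPM for correlations used a prior count of 2. Where a group had no count of a gene, levels are given in place of a fold change, and the bound used in a list's median is taken against a floor of 3 counts over the group. With 1 to 3 counts a ratio with its 95% Poisson interval is given. These floors and intervals cover counting error only, not the spread between samples.

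A set of 28 gene lists was tested with camera on edgeR z-scores (preset inter-gene correlation 0.01), adjusted over the lists. Alternatives were a correlation estimated per list and fry, both from limma 3.58.1. The lists covered p53 targets, ERK-responsive transcripts, acinar, ductal, endocrine, gastric, classical and basal tumour-subtype, mesenchymal, fibroblast, leukocyte, endothelial, adipocyte, erythroid and mesothelial or smooth muscle genes. Others were proliferation, glycolysis or hypoxia, cholesterol synthesis, interferon, cytokine, NRF2, TGF-beta and YAP, matrix-remodelling, cell-cycle inhibitor, immediate early, mitochondrially encoded, histone and sex-linked genes. Members past the threshold are counted over all tested genes and again adjusted over the list alone. For the acinar list, where 11 genes had no count in WT, the median with those genes at their bound is given as well.

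Genes named in the report were taken from a pool set by a fixed rule. It held *Kras*, *Trp53*, *Cdkn2a*, *Cdkn1a* and *Mdm2*, and per comparison the 6 largest rises and 6 largest falls among genes past the threshold. Those had to have both replicates of the higher group above both of the lower, a mean of at least 10 CPM in the higher group and a symbol that is not a clone or predicted name. Per list and comparison, the 3 members with the smallest p were added. *Xist* and *Ddx3y* belong to the sex-linked list and are given per library. The closing section also names other members of the lists, including those of the lists added later.

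Depth was 21019265 and 24990448 counts for WT 1 and WT 2, 12700425 and 24139310 for KC 1 and KC 2, and 35841135 and 26822116 for KPC 1 and KPC 2. A floor of 3 counts corresponded to 0.143, 0.12, 0.236, 0.124, 0.0837 and 0.112 CPM in these libraries. The most abundant transcript held between 0.848% and 1.95% of the counts of a library. Spread between replicates exceeded counting error, with a chi-square per degree of freedom of 50.3 in WT, 161 in KC and 255 in KPC over genes with at least 20 counts in the pair.

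The test was run on simulated data with the same depths, in 5 draws with 50 genes changed at each of 4 sizes. Simulated spread followed 1 trend with abundance, the same in all groups. In the deposited libraries it was unequal: 9.86%, 48.9% and 27.9% of genes were over 2-fold apart within WT, KC and KPC. The rates below may thus differ from those in the data. Of genes changed 2, 4, 8 and 16-fold, 0.4%, 19.6%, 45.6% and 60.4% were called in KC against WT, and 0.8%, 21.6%, 47.2% and 61.6% in KPC against WT. False calls averaged 1.2 of 64.2, 1.8 of 67.4 and 2.2 of 70.6 in the 3 comparisons. Camera called a list of 20 genes shifted 2-fold in 5, 5 and 4 of 5 draws, and called 1, 0 and 1 of 250 unshifted lists. Simulated genes varied independently of each other. These draws therefore do not show how often the preset correlation calls unshifted lists of correlated genes.

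Alternatives were DESeq2 size factors, upper-quartile scaling and library totals in edgeR, no filter and a stricter filter (at least 1 CPM and 10 counts), the DESeq2 1.42.0 Wald test and limma-voom. A fit of only the 4 samples compared, a replicate block, a test against a fold change of 1.5 and a fit without each library were also run. A library left out leaves 1 sample in its group, which is then assumed to vary like the others. Fits without genes of chromosomes X and Y and with library quality weights in limma-voom were added after the data were seen, as were B cell, T cell, lymph node stroma and spleen gene lists used only in the closing section. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.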

Results

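RNA was sequenced from 6 mouse samples whose labels give pancreatic tissue as the source and pancreatic duct epithelium as the cell type. The samples form 3 groups of 2: WT, a control with neither mutation, KC, which carries a KRAS mutation, and KPC, which carries KRAS and P53 mutations. KC and KPC are the usual names of mouse models of pancreatic ductal adenocarcinoma (PDA), in which a mutant *Kras* allele is expressed in the pancreas without or with a mutant *Trp53* allele. The values were read counts per gene for 38087 genes, of which 23906 had enough counts to be tested. Total counts per library were 21019265 and 24990448 in WT, 12700425 and 24139310 in KC, and 35841135 and 26822116 in KPC. Levels below are normalised CPM, read counts scaled to the library total, given as the mean ± SD of the 2 libraries of a group, and log2 fold changes carry their standard error. Adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for gene lists from camera. The labels do not state whether the 2 samples of a group came from separate animals. The p-values thus measure only the spread between these samples, which in WT and KPC may be technical.

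The libraries differed within groups as well as between them. Across genes, the log2 CPM of WT 1 and WT 2 correlated with r = 0.974, that of KPC 1 and KPC 2 with r = 0.927 and that of KC 1 and KC 2 with r = 0.852; genes are not independent replicates. KC 2 was closer to KPC 1 and KPC 2 (r = 0.941 with each) than to KC 1. Counts were found in 18369 genes in KC 1, against 28120 to 30603 genes in the other 5 libraries. *Xist*, the X-inactivation transcript of female cells, stood at 1.02 and 1.56 CPM in WT 1 and WT 2, 4330 and 1.63 CPM in KC 1 and KC 2, and 1970 and 2150 CPM in KPC 1 and KPC 2. The Y-linked gene *Ddx3y* was measured at 124 and 127 CPM in WT 1 and WT 2 and at 85.3 CPM in KC 2, and had no count in the other 3 libraries. The values of both genes argue against a single animal as the source of KC 1 and KC 2. The spread within KC may thus hold differences between animals and sexes.

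The genes named in the genotypes showed no detectable difference in transcript level. Comparisons with WT below rest on libraries whose ductal transcripts summed to 55.3 and 84.4 CPM, against 4850 to 11900 CPM in KC and KPC. *Kras*, the small GTPase (chromosome 6, 145216699 to 145250239, mm10), measured 82.0 ± 2.32 CPM in WT, 65.2 ± 16.6 CPM in KC and 96.5 ± 22.1 CPM in KPC. *Trp53*, the gene of the p53 tumour suppressor (chromosome 11, 69580359 to 69591873), measured 71.9 ± 27.0, 40.3 ± 3.92 and 67.7 ± 13.95 CPM in WT, KC and KPC. Adjusted p for *Kras* was 0.586 in KC against WT, 0.713 in KPC against WT and 0.801 in KPC against KC (edgeR). For *Trp53* it was 0.23, 0.915 and 0.801. Counts per gene do not show whether the transcripts carry a mutation. *Mdm2*, whose product marks p53 for degradation (chromosome 10, 117688875 to 117710758), lay at 82.2 ± 7.38, 71.5 ± 3.06 and 72.1 ± 8.86 CPM in WT, KC and KPC, with adjusted p from 0.7 to 1. *Cdkn2a*, which encodes the INK4A and ARF tumour suppressors (chromosome 4, 89274471 to 89294653), measured 2.03 ± 0.185 CPM in WT, 12.8 ± 0.966 CPM in KC and 27.9 ± 32.3 CPM in KPC. Its adjusted p was 0.18 in KC against WT and 0.0697 in KPC against WT (edgeR), but 0.0339 and 0.000814 in DESeq2, 0.000302 and 1.11e-07 in edgeR with no filter on low counts, and 0.0211 and 0.00756 without KPC 2. *Cdkn1a*, the cyclin-dependent kinase inhibitor induced by p53 (chromosome 17, 29090976 to 29100727), rose from 17.1 ± 2.43 CPM in WT to 71.2 ± 21.3 CPM in KC and 97.6 ± 14.35 CPM in KPC. Its log2 fold change was 2.06 ± 0.34 in KC (adjusted p = 0.0221) and 2.51 ± 0.34 in KPC (adjusted p = 0.00837; edgeR). Without WT 1 the adjusted p of *Cdkn1a* was 0.182 in KC and 0.0625 in KPC, and without WT 2 it was 0.0975 in KC.

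By their labels, KC and WT differ by the KRAS mutation. The B and T cell lists added later, of 15 genes each, had median WT to KC ratios of 10 and 5.68. This comparison may thus in part be one of tissues, as taken up in the closing section. Summed transcripts of acinar, ductal, endocrine and gastric-type epithelial cells were higher in KC than in the libraries labelled WT. There they came to between 17.4 and 104 CPM per list and library. The endocrine and gastric list calls were lost with an estimated correlation (camera, adjusted p = 0.118 and 0.215). Of 27 interferon-stimulated genes 5 were lower. In all, 1443 of the 23906 genes passed the threshold, 1103 of them higher in KC and 340 lower. The genes that led the rise were *Tff2*, a trefoil peptide of gastric mucus, *Ins1* and *Ins2*, which encode insulin, the amylase copy *Amy2b*, *Reg1* of the regenerating family and the elastase gene *Cela2a*. *Tff2*, *Ins1*, *Amy2b* and *Reg1* had no count in WT and measured 2397 and 651, 335 and 891, 94.4 and 590, and 252 and 321 CPM in KC 1 and KC 2. *Cela2a* rose from 1 count in WT to 1035 ± 417 CPM in KC, a ratio of 45000 with a 95% counting interval from 8080 to 1780000. *Ins2* rose from 2 counts to 1454 ± 345 CPM, a ratio of 36400 with an interval from 10100 to 301000. The adjusted p of these 6 genes lay between 0.00355 and 0.033 (edgeR), and that of *Amy2b* was 0.0543 without KC 1. *Amy2b* is annotated as a pseudogene and, like the *Ins1*, *Ins2* and *Reg1* loci, has close copies that may share reads. Leading the fall were the immunoglobulin segments *Igkv3-7* and *Ighv7-1*, the interferon-stimulated gene *Ifi44l*, the olfactory receptor gene *Olfr164*, and *Hist1h2al* and *Rps3a3*, both annotated as processed pseudogenes. *Rps3a3* fell from 152 ± 10.2 CPM to 0.859 ± 0.445 CPM (adjusted p = 0.00359, edgeR). *Ifi44l* and *Hist1h2al* had no count in KC and fell from 19.6 ± 1.22 and 15.5 ± 0.488 CPM in WT (adjusted p = 0.0126 and 0.0181, edgeR). *Olfr164* fell from 18.9 ± 1.53 to 0.0777 ± 0.110 CPM (adjusted p = 0.036, edgeR), a call lost without WT 1, WT 2 or KC 1 (adjusted p = 0.0907, 0.0895 and 0.0694). *Igkv3-7*, with no count in KC, and *Ighv7-1*, lower by a ratio of 743 with an interval from 254 to 3600, rested on WT 2, at 88.25 and 102.9 CPM against 4.86 and 5.52 CPM in WT 1. Their adjusted p was 0.0402 and 0.0418, and 0.158 and 0.407 without WT 2; both calls were also lost without KC 1, KC 2 or KPC 2. The number of changed genes was 459 without WT 1, 648 without WT 2 and 5983 without KC 2, of which 38.8% were higher in KC. It was 3707 with no filter on low counts and 4114 with DESeq2.

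Genes of the pancreatic epithelium were together higher in KC, against libraries labelled WT that nearly lacked their transcripts. All 22 genes of the ductal list rose (camera, adjusted p = 1.61e-59; adjusted p = 0.0499 with an estimated correlation), and all 22 passed when adjusted over the list alone. The transcription factor genes *Onecut2*, *Sox9* and *Hnf1b* changed by log2 8.01 ± 0.49, 5.65 ± 0.35 and 6.85 ± 0.53 (adjusted p = 0.00355, 0.00355 and 0.00463, edgeR). *Sox9* measured 2.24 ± 0.394 CPM in WT and 113 ± 18.3 CPM in KC. Summed over the list, ductal transcripts came to 55.3 and 84.4 CPM in WT 1 and WT 2, against 4850 and 5130 CPM in KC 1 and KC 2. In the acinar list, 27 of 33 genes rose, and 32 when adjusted over the list alone (camera, adjusted p = 1.21e-73; adjusted p = 0.0282 with an estimated correlation). Its median log2 fold change was 11.08, or 10.33 with the 11 genes that had no count in WT set at their bound. *Gp2*, a glycoprotein of zymogen granules, went from 0.0862 ± 0.0654 to 391 ± 22.85 CPM (adjusted p = 0.00463, edgeR). Acinar transcripts summed to 17.4 and 40.4 CPM in WT and to 14500 and 16100 CPM in KC. Of the 20 endocrine genes 14 rose, and all 20 when adjusted over the list alone (camera, adjusted p = 5.38e-42; adjusted p = 0.118 with an estimated correlation). *Pyy*, the gene of peptide YY, had no count in WT and 135 ± 21.9 CPM in KC, and *Ttr*, which encodes transthyretin, rose from 2 counts to 33.2 ± 0.222 CPM, a ratio of 793 with an interval from 219 to 6550 (adjusted p = 0.00355 for each, edgeR).

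Some gastric and tumour-subtype genes were also higher in KC, while all 3 list calls were lost with an estimated correlation. In the list of gastric genes of early pancreatic neoplasia, 10 of 18 rose, and 18 when adjusted over the list alone (camera, adjusted p = 1.04e-25; adjusted p = 0.215 with an estimated correlation). *Dmbt1*, a mucin-like glycoprotein gene, rose from 1.03 ± 0.0173 to 5335 ± 1856 CPM (log2 12.33 ± 1.18, adjusted p = 0.00565, edgeR; 0.0623 without WT 1). *Gkn3*, a gastrokine gene, rose from 2 counts to 645 ± 443 CPM, a ratio of 13100 with an interval from 3620 to 108000. Of 20 genes of the classical PDA subtype 14 rose, and 17 when adjusted over the list alone (camera, adjusted p = 4.43e-30; adjusted p = 0.136 with an estimated correlation). *Hnf4a*, a transcription factor gene of the gut lineage, measured 60.3 ± 19.1 CPM in KC from 1 count in WT, a ratio of 3070 with an interval from 550 to 121000, and *Foxa2* had no count in WT and 43.8 ± 20.3 CPM in KC. Among 16 basal or squamous genes 3 rose, and 5 when adjusted over the list alone (camera, adjusted p = 0.000126; adjusted p = 0.245 with an estimated correlation). *Lamc2*, a laminin chain gene, rose from 8.86 ± 0.420 to 165 ± 69.2 CPM (adjusted p = 0.00592, edgeR). These lists rose in libraries in which the ductal list, at 4850 and 5130 CPM, was also far above WT.

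Some targets of signalling pathways were higher in KC, in libraries whose ductal transcripts summed to 4850 and 5130 CPM against 55.3 and 84.4 CPM in WT. Of 20 transcripts that rise with ERK activity 7 rose, and 16 when adjusted over the list alone (camera, adjusted p = 4.63e-10; adjusted p = 0.245 with an estimated correlation). *Epha2*, an ephrin receptor gene, rose from 6.51 ± 1.09 to 67.0 ± 12.4 CPM (log2 3.36 ± 0.33, adjusted p = 0.00576, edgeR), and *Areg*, which encodes the EGFR ligand amphiregulin, from 0.122 ± 0.110 to 14.25 ± 2.134 CPM (adjusted p = 0.011). Among 30 direct p53 targets 3 rose, *Cdkn1a*, *Perp* and *Ak1*, and 6 when adjusted over the list alone (camera, adjusted p = 0.0284; adjusted p = 0.495 with an estimated correlation). *Perp*, whose product sits in desmosomes of epithelia, rose from 1.68 ± 0.625 to 70.05 ± 46.4 CPM (adjusted p = 0.00896, edgeR), and *Ak1*, an adenylate kinase gene, from 5.87 ± 0.243 to 45.0 ± 16.3 CPM (adjusted p = 0.0165; 0.0839 without WT 1 and 0.0577 without WT 2). *Cdkn2b*, a neighbour of *Cdkn2a* that also encodes a cyclin-dependent kinase inhibitor, rose by log2 2.54 ± 0.41 (adjusted p = 0.0217, edgeR; 0.11, 0.091 and 0.0545 without WT 1, WT 2 and KC 1). It and *Cdkn1a* were the genes that rose in a list of 19 cell-cycle inhibitors and tumour suppressors, which camera did not call (camera, adjusted p = 0.603). Of 19 antioxidant targets of NRF2 4 rose, among them *Gsta4*, and of 18 TGF-beta and YAP targets 4 rose, among them the integrin gene *Itgb6*. Camera called both lists (adjusted p = 2.82e-05 and 1.21e-05; adjusted p = 0.215 and 0.34 with an estimated correlation). The immediate early gene *Fos* rose from 4.30 ± 1.16 to 37.2 ± 0.252 CPM (adjusted p = 0.00846, edgeR); 2 genes of that list of 22 rose and 1 fell, with camera adjusted p = 0.0807.

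Markers of stroma and blood cells differed as well. Of 20 fibroblast genes 4 rose, and 11 when adjusted over the list alone (camera, adjusted p = 2.37e-07; adjusted p = 0.349 with an estimated correlation), and of 22 matrix-remodelling genes 3 rose, and 12 over the list alone (camera, adjusted p = 1.41e-07; adjusted p = 0.439 with an estimated correlation). *Col1a1*, the collagen I gene, went from 151 ± 28.6 to 3463 ± 82.9 CPM (adjusted p = 0.0293, edgeR; 0.318 without WT 1 and 0.228 without WT 2). Of 24 leukocyte genes 2 fell, 1 rose and 21 did not pass. The 1 that rose was *Cd14*, a gene of myeloid cells, from 7.51 ± 3.13 to 56.5 ± 18.3 CPM (adjusted p = 0.0482, edgeR). *Ptprc*, the pan-leukocyte phosphatase gene, fell from 2155 ± 152 to 371 ± 6.40 CPM (adjusted p = 0.0415, edgeR), a call lost without WT 1, WT 2 or KC 1 (adjusted p = 0.182, 0.131 and 0.0978). *Cd4*, a T cell coreceptor gene, fell from 140 ± 0.896 to 20.8 ± 12.2 CPM (adjusted p = 0.0272, edgeR; 0.0584 without WT 1). Camera did not call the list (camera, adjusted p = 0.326), and its median log2 change, 0.037, differed in sign from its mean of -0.195 and from the direction of the test. Leukocyte transcripts summed to 7370 and 9130 CPM in WT and to 5170 and 5140 CPM in KC. In the interferon list 5 of 27 genes fell, and 18 when adjusted over the list alone (camera, adjusted p = 5.4e-10; adjusted p = 0.31 with an estimated correlation). *Ifit2* fell from 92.8 ± 6.09 to 12.4 ± 6.22 CPM (adjusted p = 0.0181, edgeR) and *Stat1* from 239 ± 0.418 to 52.7 ± 25.5 CPM (adjusted p = 0.0295; 0.0907 without WT 1 and 0.0724 without WT 2). None of 32 proliferation genes passed over all genes, while 10 were lower when adjusted over the list alone (camera, adjusted p = 1.03e-05; adjusted p = 0.46 with an estimated correlation). Camera also called 8 erythroid genes higher (1 rose; adjusted p = 0.000117; adjusted p = 0.245 with an estimated correlation) and 13 histone and other non-polyadenylated genes lower (1 fell; adjusted p = 0.00155; adjusted p = 0.495 with an estimated correlation).

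**Figure D1:**
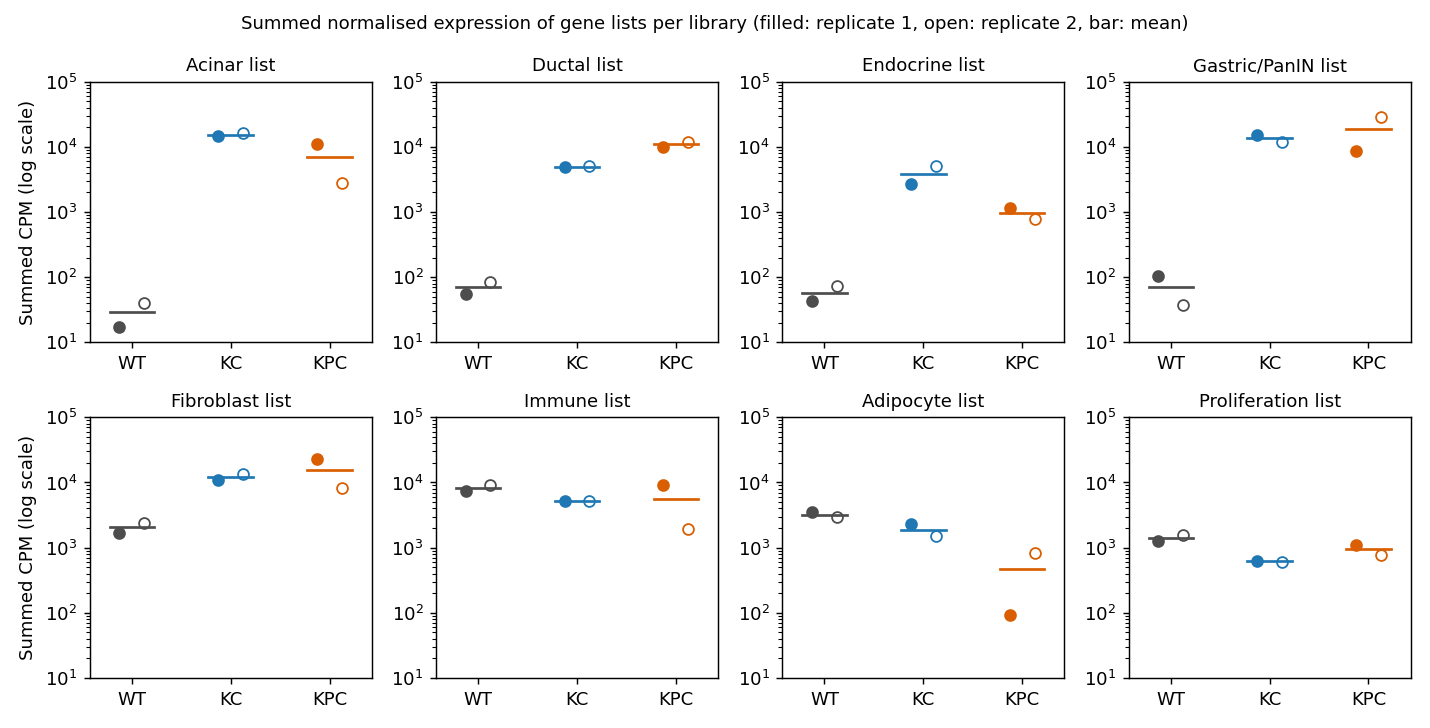
Summed normalised CPM of 8 gene lists (log scale) in each library, with filled points for replicate 1, open points for replicate 2 and a bar at the mean of the 2. The ductal list lies at 55.3 and 84.4 CPM in WT and at or above 4850 CPM in the other 4 libraries, while the immune list spans 1940 to 9220 CPM over all 6.

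KPC and WT differ, by their labels, by the mutations of KRAS and P53. B and T cell lists added later, of 15 genes each, had median WT to KPC ratios of 58.8 and 24.7. The comparison may thus in part be one of tissues, as taken up in the closing section. Camera called the acinar, ductal, endocrine, gastric, classical and basal lists higher in KPC as in KC, all but the acinar call being lost with an estimated correlation (adjusted p from 0.0529 to 0.239), while 15 of 27 interferon-stimulated genes and 9 of 24 leukocyte genes were lower. In total 2439 genes passed the threshold, 1652 higher in KPC and 787 lower (67.7% higher). With upper-quartile scaling the split was 1367 higher and 1054 lower (56.5% higher). *Tff2* and 3 genes of the regenerating family, *Reg1*, *Reg3b* and *Reg2*, led the rise together with *Gabrp*, a GABA receptor subunit gene, and *Cldn2*, a tight junction gene. *Tff2*, *Reg1*, *Reg3b*, *Reg2* and *Gabrp* had no count in WT and measured 270 and 1573, 836 and 438, 720 and 270, 396 and 9.47, and 191 and 105 CPM in KPC 1 and KPC 2 (adjusted p from 0.00224 to 0.0342, edgeR). The adjusted p of *Reg2* was 0.0648 without KC 1 and 0.0707 without KC 2. *Cldn2* rose from 1 count in WT to 561 ± 50.75 CPM, a ratio of 26600 with an interval from 4770 to 1050000 (adjusted p = 0.00224, edgeR). The genes that led the fall were *Ifi44l*, *Ighv7-1*, *Hist1h2al*, the interleukin-22 binding protein gene *Il22ra2*, the desmosomal cadherin gene *Dsc3* and *Havcr1*. *Ifi44l* had no count in KPC, and *Dsc3* fell from 139.5 ± 5.32 to 0.320 ± 0.310 CPM (log2 -8.78 ± 1.28, adjusted p = 0.0105, edgeR). *Hist1h2al*, *Havcr1*, *Il22ra2* and *Ighv7-1* each had 2 or 3 counts in KPC, and were lower by ratios of 433 (interval 120 to 3590), 374 (103 to 3090), 1280 (354 to 10600) and 1050 (359 to 5100). In edgeR *Il22ra2* was lost without KPC 1 or KPC 2 (adjusted p = 0.128 and 0.159), and *Ighv7-1* without WT 2, KPC 1 or KPC 2 (adjusted p = 0.298, 0.114 and 0.087). The number of changed genes was 1014 without WT 1, 1266 without WT 2, 4401 without KC 1 and 4277 without KC 2. It was 4504 with no filter on low counts, 5113 with DESeq2 and 5189 with only the 4 samples compared.

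All 22 ductal genes rose in KPC (camera, adjusted p = 1e-59; adjusted p = 0.0529 with an estimated correlation), also when adjusted over the list alone. *Krt7*, a duct keratin gene (chromosome 15, 101411043 to 101430313), went from 2.96 ± 0.565 CPM in WT to 524 ± 66.7 CPM in KPC (log2 7.46 ± 0.53, adjusted p = 0.00224, edgeR). *Onecut2* rose by log2 9.66 ± 0.53 and *Sox9* by log2 6.44 ± 0.36 (adjusted p = 0.00224 for each, edgeR). The list summed to 10100 and 11900 CPM in KPC 1 and KPC 2. In the acinar list 27 of 33 genes rose, and 31 when adjusted over the list alone (camera, adjusted p = 8.76e-45; adjusted p = 0.0385 with an estimated correlation). Acinar transcripts summed to 11100 CPM in KPC 1 and 2820 CPM in KPC 2. Among 20 endocrine genes 14 rose, and 18 over the list alone (camera, adjusted p = 9.09e-28; adjusted p = 0.16 with an estimated correlation). *Ins2* measured 99.0 ± 37.9 CPM in KPC, a ratio of 2400 with an interval from 665 to 19800. Of 18 gastric genes 11 rose (18 over the list alone), of 20 classical-subtype genes 16 (19 over the list alone) and of 16 basal or squamous genes 6, with 1 lower (8 and 1 over the list alone). Camera called the 3 lists at adjusted p = 8.23e-19, 1e-25 and 1.29e-05; with an estimated correlation they had adjusted p = 0.239, 0.168 and 0.168. *Hnf4a* reached 166 ± 93.4 CPM, a ratio of 7690 with an interval from 1380 to 304000, *Dmbt1* 11080 ± 6246 CPM (adjusted p = 0.00289) and *Lamc2* 435 ± 55.2 CPM (log2 5.62 ± 0.45, adjusted p = 0.00232, edgeR).

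Targets of signalling pathways were compared in libraries whose ductal transcripts summed to 10100 and 11900 CPM in KPC, against 55.3 and 84.4 CPM in WT. Of the 20 ERK-responsive genes 14 rose in KPC, and 17 when adjusted over the list alone. Camera called this list higher (adjusted p = 1.09e-13), but not with an estimated correlation (adjusted p = 0.168). *Epha2* rose by log2 4.50 ± 0.34 (adjusted p = 0.00232), *Etv4*, an ETS transcription factor gene, by log2 5.23 ± 0.59 (adjusted p = 0.00526) and *Phlda1* by log2 3.79 ± 0.39 (adjusted p = 0.00382, edgeR). Among the 30 p53 targets 7 rose and 1 fell, and 8 and 3 when adjusted over the list alone (camera, adjusted p = 0.0187; adjusted p = 0.433 with an estimated correlation); *Perp* rose to 95.35 ± 2.74 CPM (adjusted p = 0.00465). *Cdkn2b* rose by log2 3.77 ± 0.43 (adjusted p = 0.00526, edgeR), as did 2 others of the 19 cell-cycle inhibitor and tumour suppressor genes (camera, adjusted p = 0.317). Of 19 NRF2 targets 7 rose, *Akr1b8* by log2 4.24 ± 0.51 (adjusted p = 0.00611), and of 18 TGF-beta and YAP targets 7 rose, *Ajuba* by log2 3.39 ± 0.36 (adjusted p = 0.00426, edgeR). Over the list alone 10 and 12 rose (camera, adjusted p = 1.29e-05 and 1.04e-07; adjusted p = 0.168 and 0.261 with an estimated correlation). Cholesterol synthesis and glycolysis or hypoxia genes were called higher, with 4 of 19 and 4 of 22 passing and 8 and 5 over the list alone (camera, adjusted p = 0.000399 and 0.00274; adjusted p = 0.347 for each with an estimated correlation). *Dhcr24*, a reductase of cholesterol synthesis, rose from 29.3 ± 0.682 to 203 ± 62.1 CPM (adjusted p = 0.00527), and *Car9*, a hypoxia-induced carbonic anhydrase gene, from 1.65 ± 0.835 to 68.0 ± 46.75 CPM (adjusted p = 0.0105, edgeR). Of 22 immediate early and heat shock genes 5 rose and 2 fell (camera, adjusted p = 0.0377; adjusted p = 0.421 with an estimated correlation); *Fos* rose to 80.1 ± 17.9 CPM (adjusted p = 0.00258, edgeR).

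In the leukocyte list 9 of 24 genes fell in KPC and 1 rose (camera, adjusted p = 0.00965, lower; adjusted p = 0.534 with an estimated correlation). Its median log2 change was 0.925 and its mean -0.851, so the median differed in sign from the test. DESeq2 called 10 of the 24 genes lower and 3 higher. The myeloid gene *Cd14* averaged 7.51 ± 3.13 CPM in WT and 125 ± 88.9 CPM in KPC. *Cd4* fell from 140 ± 0.896 to 3.42 ± 0.988 CPM (log2 -5.36 ± 0.55, adjusted p = 0.00389, edgeR). *Cd79a*, a subunit of the B cell receptor, fell from 223 ± 62.2 to 2.98 ± 2.20 CPM (edgeR, adjusted p = 0.014; 0.0506 without KPC 2), and *Ptprc* from 2155 ± 152 to 219 ± 116 CPM (adjusted p = 0.0142; 0.0529 without KPC 2). Leukocyte transcripts summed to 9220 CPM in KPC 1 and 1940 CPM in KPC 2. In WT, where B and T cell genes were higher than in KPC, they summed to 7370 and 9130 CPM. Of 27 interferon-stimulated genes 15 fell, and 19 when adjusted over the list alone (camera, adjusted p = 2.01e-14; adjusted p = 0.168 with an estimated correlation). *Stat1* fell to 25.8 ± 3.32 CPM, *Ifit2* to 11.6 ± 2.66 CPM and *Usp18* from 81.4 ± 21.8 to 8.81 ± 5.34 CPM (adjusted p = 0.00734, 0.0106 and 0.0134, edgeR). Adipocyte transcripts summed to 3530 and 2910 CPM in WT and to 92.7 and 833 CPM in KPC; 1 of the 12 genes, *Fabp4*, fell (camera, adjusted p = 4.05e-05; adjusted p = 0.421 with an estimated correlation). *Fabp4* had adjusted p = 0.0395, and 0.0726, 0.0567 and 0.0635 without WT 1, WT 2 and KPC 1 (edgeR). Of 20 fibroblast genes 7 rose and of 22 matrix-remodelling genes 8, with 13 and 19 over the list alone (camera, adjusted p = 4.55e-07 and 4.46e-09; adjusted p = 0.347 for each with an estimated correlation). *Mmp7*, the matrilysin gene, rose from 0.595 ± 0.404 to 434 ± 343 CPM (adjusted p = 0.0104) and *Timp1*, a metalloproteinase inhibitor gene, from 0.677 ± 0.457 to 37.1 ± 32.85 CPM (adjusted p = 0.0131, edgeR). Camera also called erythroid genes higher (2 of 8 rose), mesenchymal genes higher (1 of 19 rose) and proliferation genes lower (0 of 32 passed), at adjusted p = 9.61e-05, 0.00965 and 0.00809, and at adjusted p = 0.239, 0.534 and 0.534 with an estimated correlation.

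Most of the genes called in KC were called in KPC as well. Both comparisons shared 1339 genes with the same direction, 1030 higher and 309 lower, and none with opposite directions; these were 92.8% of the KC calls. Independent lists of these sizes would share 76.2 higher and 11.2 lower genes, a number that takes no account of the shared WT libraries. Fold changes of the 2 comparisons correlated across genes with r = 0.856 and had a covariance of 4.76. In 20 simulations with no group effect, where both comparisons shared 2 simulated WT libraries, these were 0.497 and 0.704 (a covariance difference of 4.06). All simulated libraries had the same mean for each gene. The simulations thus lack the profile of the deposited WT libraries, and do not show how much of the overlap that profile brings. The 2 WT libraries could not be split between the comparisons, so part of the overlap may come from the shared controls. The shared number was 435 without WT 1, 628 without WT 2 and 2260 without KC 2, and 3060 with no filter and 3233 with DESeq2.

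**Figure D2:**
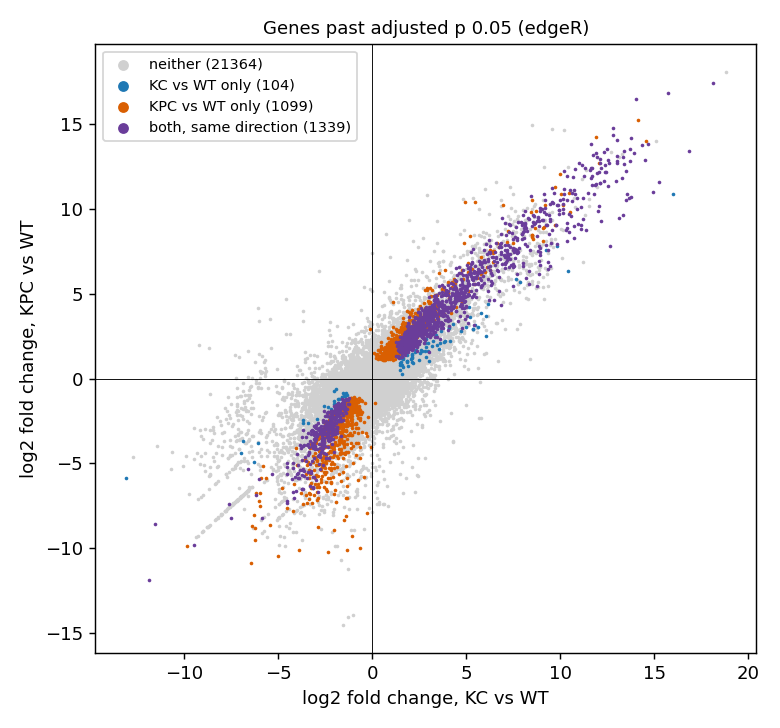
Log2 fold change of each tested gene in KC against WT (horizontal axis) and in KPC against WT (vertical axis), coloured by whether it passed an adjusted p of 0.05 in edgeR. The 1339 genes called in both lie in the quadrants of shared sign, 104 were called in KC alone and 1099 in KPC alone; fitted values of genes with no count in WT depend on the prior count.

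KPC and KC differ by the P53 mutation, by their labels. These libraries did not hold transcripts of duct epithelium alone. Fibroblast transcripts summed to 10800 and 13500 CPM in KC 1 and KC 2, and to 23100 and 8350 CPM in KPC 1 and KPC 2. Leukocyte transcripts in this order summed to 5170, 5140, 9220 and 1940 CPM. Differences between the groups, or their absence, may thus reflect the mix of cells, which was not tested. In edgeR no gene passed the threshold; 1344 genes had an unadjusted p under 0.05, limma-voom also called 0, and DESeq2 called 301, of which 65 were higher and 236 lower in KPC. With no filter on low counts edgeR called 602 genes. Simulated counts gave calls for 0.8% of genes changed 2-fold, 22.8% of those changed 4-fold and 67.6% of those changed 16-fold. Their spread was the same in all groups, unlike that of the deposited libraries. Camera called 15 of the 28 lists, and with an estimated correlation none; without KC 2 it called 5. The libraries also differed in sex-linked transcripts: the list summed to 4330 and 320 CPM in KC 1 and KC 2, and *Ddx3y*, at 85.3 CPM in KC 2, had no count in KC 1, KPC 1 or KPC 2.

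No direct target of p53 was called between KPC and KC. None of the 30 passed in edgeR or when adjusted over the list alone, and camera gave adjusted p = 0.618 for a median log2 difference of 0.132. *Cdkn1a* differed by log2 0.46 ± 0.32 (95% interval -0.32 to 1.23) and *Mdm2* by log2 0.01 ± 0.26 (-0.61 to 0.64), with adjusted p = 0.817 and 1 (edgeR). The sign of the *Mdm2* difference turned under other scalings. *Zmat3* and *Tnfrsf10b*, which encode an RNA-binding protein and a death receptor, had log2 differences of 1.14 ± 0.34 and 1.16 ± 0.36 (adjusted p = 0.801 for each, edgeR). Of the ERK-responsive genes none passed, and the list was called higher in KPC, where ductal transcripts summed to 10100 and 11900 CPM against 4850 and 5130 CPM in KC (median log2 0.722; camera, adjusted p = 0.000131; adjusted p = 0.507 with an estimated correlation). *Epha2* measured 67.0 ± 12.4 CPM in KC and 147 ± 23.1 CPM in KPC, and the cyclin gene *Ccnd1* 128 ± 11.6 and 248 ± 31.0 CPM (adjusted p = 0.801 for each, edgeR).

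The acinar and endocrine lists were called lower in KPC than in KC and the ductal list higher, while none of their genes passed in edgeR over all genes. For the acinar list the median log2 difference was -1.51 (camera, adjusted p = 6.75e-23; adjusted p = 0.2 with an estimated correlation), and 6 genes were lower when adjusted over the list alone. Acinar transcripts summed to 14500 and 16100 CPM in KC 1 and KC 2, 11100 CPM in KPC 1 and 2820 CPM in KPC 2. *Reg1*, of the same list and chosen after its values were seen, measured 287 ± 49.1 CPM in KC and 637 ± 281 CPM in KPC (adjusted p = 0.801, edgeR). *Cela2a* measured 1035 ± 417 CPM in KC and 82.2 ± 32.1 CPM in KPC, a log2 difference of -3.65 ± 0.55, and *Cela1* and *Ctrl*, also digestive protease genes, differed by log2 -3.33 ± 0.59 and -2.50 ± 0.44 (adjusted p = 0.801 for each, edgeR). DESeq2 called these 3 genes (adjusted p = 4.81e-09, 2.52e-05 and 0.00075). In the endocrine list, with a median of -1.25 (camera, adjusted p = 8.94e-11; adjusted p = 0.458 with an estimated correlation), 4 genes were lower over the list alone. *Ins2* measured 1454 ± 345 CPM in KC and 99.0 ± 37.9 CPM in KPC, and *Ins1* 613 ± 393 and 57.5 ± 29.7 CPM; DESeq2 gave adjusted p = 2.5e-12 and 0.000196 where edgeR gave 0.801 for each. Summed endocrine transcripts were 2660 and 5140 CPM in KC and 1170 and 783 CPM in KPC. The ductal list had a median of 1.005 (camera, adjusted p = 2.26e-09; adjusted p = 0.458 with an estimated correlation), and 3 genes were higher over the list alone. *Krt7* measured 112 ± 50.69 CPM in KC and 524 ± 66.7 CPM in KPC, *Onecut2* 261 ± 78.75 and 825 ± 17.9 CPM, and the bicarbonate transporter gene *Slc4a4* 88.1 ± 11.9 and 220 ± 15.6 CPM. DESeq2 called the 3 genes at adjusted p = 0.00145, 0.0144 and 0.0262, and edgeR gave 0.801 for each.

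Other lists called in KPC against KC had no gene past the edgeR threshold. The cholesterol list was called higher (median log2 0.862; camera, adjusted p = 2.26e-09; adjusted p = 0.458 with an estimated correlation), with 7 of 19 genes higher over the list alone. *Dhcr24* measured 72.2 ± 0.547 CPM in KC and 203 ± 62.1 CPM in KPC (log2 1.49 ± 0.31, adjusted p = 0.801, edgeR; 0.0278 in DESeq2), and *Sqle*, the squalene epoxidase gene, 34.4 ± 2.48 and 76.6 ± 11.7 CPM. Glycolysis or hypoxia, TGF-beta and YAP, matrix-remodelling, basal or squamous, proliferation and histone lists were called higher (camera, adjusted p = 6.39e-05, 0.00161, 0.00526, 0.0195, 0.00655 and 0.0337; adjusted p from 0.458 to 0.744 with an estimated correlation). Summed glycolysis or hypoxia, basal or squamous and proliferation transcripts were higher in both KPC libraries than in both KC libraries. Matrix-remodelling transcripts summed to 1630 and 2010 CPM in KC, 5360 CPM in KPC 1 and 1530 CPM in KPC 2. For TGF-beta and YAP transcripts the sums in this order were 1820, 1990, 4380 and 2020 CPM. For histone transcripts they were 7740, 4580, 6890 and 4590 CPM. Fry called no list in this comparison. *Lamc2* differed by log2 1.40 ± 0.37 and *Tpi1*, a glycolytic enzyme gene, by log2 1.02 ± 0.30 (adjusted p = 0.801 for each, edgeR). Adipocyte, interferon, leukocyte and sex-linked lists were called lower (camera, adjusted p = 1.16e-10, 6.64e-05, 5.51e-05 and 0.013; adjusted p from 0.458 to 0.541 with an estimated correlation). The leukocyte list had a median log2 difference of 0.362 and a mean of -0.656. *Cd4* measured 20.8 ± 12.2 CPM in KC and 3.42 ± 0.988 CPM in KPC, and *Cd79a* 30.6 ± 28.75 and 2.98 ± 2.20 CPM (adjusted p = 0.801 for each in edgeR, 0.000903 and 0.00612 in DESeq2). *Dsc3*, of the basal list, went against that list, with 18.9 ± 20.2 CPM in KC and 0.320 ± 0.310 CPM in KPC.

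**Figure D3:**
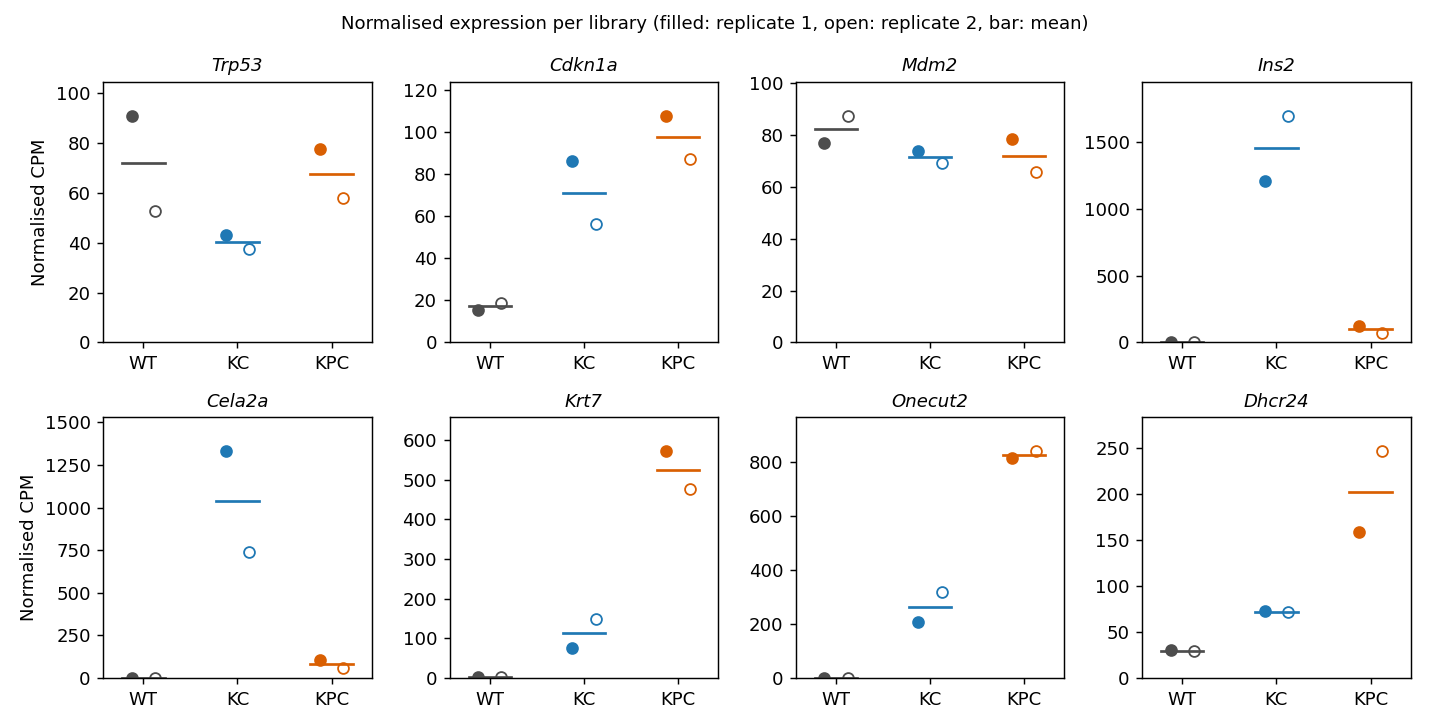
Normalised CPM of 8 genes in each library (filled points, replicate 1; open points, replicate 2; bar, mean of the 2), on axes that start at 0. *Ins2* and *Cela2a* are lower in both KPC libraries than in both KC libraries and *Krt7*, *Onecut2* and *Dhcr24* higher, each with an edgeR adjusted p of 0.801; *Mdm2* lies between 65.8 and 87.5 CPM in all 6.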

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

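No test in this part was chosen after its results were seen, and the values below were listed by a rule fixed beforehand. Each sample of a group had to move the opposite way from each sample of another, against the mean of the same control. The rule was applied to the lists and the named genes, a pool that takes list members by their smallest p in a comparison. A test of KPC against KC is thus not independent of how the genes below were chosen. *Dhcr7*, a reductase of cholesterol synthesis, averaged 16.2 CPM in KC, below 23.0 CPM in WT, and 36.7 CPM in KPC. *Gapdh*, a glycolytic enzyme gene, averaged 338 CPM in KC, below 437 CPM in WT, and 840 CPM in KPC. The difference between the effects, tested as KPC against KC, was log2 1.18 ± 0.28 and 1.31 ± 0.40, with adjusted p = 0.801 for each in edgeR and 0.0641 and 0.0679 in DESeq2.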

How the results depend on the processing

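Fits with library quality weights and without X and Y genes were chosen after results were seen. The counts of calls rose with no filter to 3707 in KC against WT, 4504 in KPC against WT, 602 in KPC against KC and 3060 shared, and with DESeq2 to 4114, 5113, 301 and 3233. KPC against WT gave 5189 with only the 4 samples compared and 6458 with quality weights. Leaving out a library gave 459 (without WT 1) to 5983 (without KC 2), 1014 (without WT 1) to 4401 (without KC 1), and 435 to 2260 shared; KPC against KC stayed at 0. The cause was not tested. Lists called in KC against WT, KPC against WT and KPC against KC numbered 2, 1 and 0 with an estimated correlation and 6, 11 and 0 with fry. In KPC against KC they ranged from 5 (without KC 2) to 21 (without KC 1).

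With a replicate block the counts were 1265, 2109, 0 and 1203 shared. Differences between replicates correlated at -0.097 for WT and KC, -0.133 for WT and KPC and 0.051 for KC and KPC, and the labels do not pair the samples. Without X and Y genes the counts were 1398, 2366 and 0.

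Log2 fold changes that turned sign were, in KPC against WT, *Kras* at -0.027 without KPC 1 (0.471 without KPC 2) and *Trp53* at 0.348 without WT 1 (-0.428 without WT 2) and 0.126 without KPC 2. In KPC against KC they were *Cdkn2a* at -1.348 without KPC 1 (2.066 without KPC 2) and *Mdm2* at -0.113 without KPC 1 (0.21 without KPC 2), -0.015 without KC 2, -0.02 with DESeq2 or its size factors and -0.248 with library totals. None had passed the threshold, and the cause was not tested. Over the named genes and the settings run for them, 1304 values kept their direction and their side of the threshold, 29 passed it newly, 50 no longer passed and 9 turned sign. Depth limits genes under the floors of 0.0837 to 0.236 CPM.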

Other observations

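The tests of dilution, of genotype alone and of X and Y genes and the simulation for sex were chosen after results were seen, as were the B and T cell lists, and the other 5 tests below were written before their values. Several gene groups were not called against WT. In KC against WT, camera did not call mesenchymal, endothelial, adipocyte, mesothelial or smooth muscle, glycolysis or hypoxia, cholesterol and cytokine genes (adjusted p = 0.0584, 0.0998, 0.304, 0.603, 0.32, 0.589 and 0.186), nor mitochondrially encoded and sex-linked genes (0.161 and 0.434). In KPC against WT it did not call endothelial, mesothelial or smooth muscle, cytokine, mitochondrially encoded, histone and sex-linked genes (adjusted p = 0.537, 0.532, 0.363, 0.321, 0.0671 and 0.0595). Among the cytokine genes, *Cxcl5*, a chemokine that draws neutrophils, rose by log2 7.35 ± 1.03 in KC (adjusted p = 0.0141, edgeR) and 7.34 ± 1.03 in KPC (adjusted p = 0.00937), while *Ccl5*, a T cell chemokine, fell by log2 -5.77 ± 0.85 in KPC (adjusted p = 0.0108; 0.0524 without KPC 1). *Egr3* fell in KC and KPC, from 45.0 CPM in WT to 4.60 and 4.57 CPM (adjusted p = 0.0231 and 0.0149, edgeR; 0.09 and 0.058 without WT 1, and 0.0779 in KPC without KPC 2).

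In KPC against KC the gastric, classical, mesenchymal, fibroblast, endothelial, erythroid and mesothelial or smooth muscle lists were not called (camera, adjusted p = 0.499, 0.418, 0.0901, 0.418, 0.0579, 0.669 and 0.0758). Nor were the cytokine, NRF2, cell-cycle inhibitor, immediate early and mitochondrially encoded lists (camera, adjusted p = 0.419, 0.4, 0.228, 0.4 and 0.499). Mesothelial and smooth muscle transcripts summed to 365 CPM in KPC 1 and 3140 CPM in KPC 2, and mesenchymal transcripts to 15800 and 3090 CPM.

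For the near absence of acinar, ductal and endocrine transcripts in the libraries labelled WT, leukocyte RNA diluting an intact pancreas was weighed. It would lower fibroblast and endothelial genes (without *Thy1* and *Pecam1*, which leukocytes express) as far as the pancreatic lists. Over pairs of a WT and a KC library, the lowest level of these genes was 11.4% of KC. The highest of the acinar, ductal and endocrine lists was 2.73%. That argues against dilution by leukocytes alone, and not against lymphoid tissue that brings stroma of its own. Duct epithelium of any genotype would express *Epcam*, *Cdh1*, *Krt8* and *Krt18*, whose median in WT was 1.28% of KC. That argues against genotype alone with WT being duct epithelium as labelled. These genes belong to the ductal list, so their level is part of the pattern and not independent of it. As a hypothesis, lymphoid tissue RNA in the WT libraries fits: 15 B cell and 15 T cell genes, each of which was also above 1 CPM in both KC libraries, had median WT to KC ratios of 10 and 5.68. Of these 9 and 1 were called higher in WT against KC and 15 and 13 against KPC (lymph node stroma, ratio to KC 1.84, 0 and 4 of 9; spleen, 4.04, 0 and 2 of 4), and of the most abundant, *Ighm* (806 and 1260 CPM in WT) reached 1060 CPM in KC 1 and *Sell* (525 and 545 CPM) was called in neither comparison (adjusted p = 0.21 and 0.14, edgeR). If so, comparisons with WT would in part compare tissues; no sort or gate is named in the labels, and the test does not show how such RNA came to be there.

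The distance of KC 1 from KC 2 was weighed against depth, RNA amount and a background. Lower depth was excluded, since KC 2 thinned to the depth of KC 1 still had a count in 1.58 times as many genes. Few RNA molecules behind KC 1 would make it miss rare transcripts. Of 787 genes at 1 to 2 CPM in both KPC libraries, 45.1% had no count in KC 1, against 0.254% in thinned KC 2. This went with the explanation, but the share is part of the low number of genes with a count in KC 1. It is thus not independent of the pattern. Nor was the distance confined to rare transcripts. Of 11601 genes averaging at least 10 CPM, 24.7% were over 2-fold apart in KC, against 16.2% in KPC and 4.02% in WT. A low background absent from KC 1 would lower the mean of the 787 genes there. That mean was 0.971 of the mean in KC 2 (95% interval 0.875 to 1.08). Genes higher in KC 1 for other reasons can hold such a mean up, so a background was not excluded. No biological explanation was tested.

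Sex-linked transcripts differ between KPC and WT, so sex was weighed as a source of the KPC against WT calls. X and Y genes made up 2.67% of the calls. The fit without them still tested 23229 genes, against 23906 in the main fit, so they were too few to make up most calls. For sex behind the other calls, KC 2, which like WT has Y-linked transcripts, kept a median 0.82 of the log2 fold change of KPC (quartiles 0.70 to 0.94) over 2374 genes outside X and Y. With no group effect, 20 simulations that shared simulated WT libraries gave medians from 0.46 to 0.53. They did not hold the profile of the deposited WT libraries, which both fold changes share. X and Y genes were thus not the bulk of the calls, which their number fixed beforehand and which does not bear on sex. Sex behind the other calls stays open, since KC 2 is the single mutant library with Y-linked transcripts.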
